A study of Mus musculus with 6 samples.

How the data were processed

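The series measured mRNA in cells of the mouse microglial line BV2 on single-colour Agilent arrays labelled with Cy3. Per the labels, 3 samples received IL-4 at 10 ng/ml for 24 hr and 3 received PBS for 24 hr, with 1 array per sample. The series' design text calls the control untreated while the sample labels say PBS, and PBS is used here. A description field of the labels mentions human blood, which goes against every other label, and it was not used. Groups and replicate numbers were taken from the labels.

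The deposited scanner files hold spot intensity values on a linear scale, made by the authors with Agilent Feature Extraction 11.0.1.1, per the file headers. The processed signal used here is background subtracted and detrended within each array by that program, per the file headers, and is not normalized between arrays. The authors also deposited a value table of 39485 rows, which from its values is on a log2 scale with the same median of 6.92 in all 6 columns. Its normalization is not given in the sources used here. Each of its columns correlated at 0.999 or above, across probes, with the log2 processed signal of the same array, and the table was used only as an alternative.

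Each array had 44397 spots, of which 43020 were not controls. Spots with an outlier flag were left out (87 to 394 per array), no spot was saturated, and copies of a probe were averaged. This gave 39429 probes, of which 399 had 10 copies. The log2 processed signal was set relative to its 75th percentile on each array. The share of probes well above background was 87.9% for IL-4 replicate 1, 97.0% for IL-4 replicate 2, 96.6% for IL-4 replicate 3, 98.0% for PBS replicate 1, 88.9% for PBS replicate 2 and 94.0% for PBS replicate 3. The median SD of log2 signal between copies of a probe was 0.0663 to 0.0943. Probes well above background on every array of at least 1 group were tested. Gene symbols came from matching the accession of each probe, without version, to a RefSeq table of the mouse assembly GRCm38.p6, which named 27234 probes (69.1%) and left 12195 under the name in the scanner file. The file headers give an earlier annotation build for the probes, so no coordinates are printed. The brightest tested probe stood for a gene.

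Groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with IL-4 minus PBS as the contrast and no block. The test covered 29752 genes or unnamed transcripts, 19142 of them with a symbol, measured by 35979 probes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and all adjusted p-values of genes are from this limma fit unless another is named. SE is that of the fit, and SD is over the 3 arrays of a group. A bound on the fold was not needed, since no named gene was below background on every array of a group. The files' records place the 3 IL-4 arrays and PBS replicate 1 on slide 1 and PBS replicates 2 and 3 on slide 2. The fit was therefore repeated with slide as a block, where the IL-4 effect equals the difference within slide 1, and on slide 1 alone.

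Gene lists for 39 pathways, states and cell types were fixed before the data were examined, as were the tests, most alternatives and the rule for named genes. Lists of at least 5 tested genes were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry, each adjusted over the lists. The rule named the 10 largest rises and 10 largest falls among called genes whose groups did not overlap, passing over names that are only an accession, clone or gene model. It also named 18 genes of IL-4 response and inflammation whatever their values, up to 4 called members of a list that passed or had at least 3 called members, and up to 3 of the brightest markers of each other cell type. Of the genes it named, 1 is not reported here. The list members Clec7a, Il12b, Cxcl11, Mx1, Mx2, Oas1b, Ifi205, Ifi203, Cd68, Amd1, Ca9, Ca12 and Hspa1b had no matched probe and were not analysed here.

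The steps were tested on simulated data with 29488 genes and 100 changed genes per fold size. With no slide difference, the fit without a block recovered 97% of 2-fold and 100% of 4-fold changes, and 7.08% of its calls were false. The fit with slide as a block then recovered 84% and 100%, and 10.7% of its calls were false. With the observed slide differences shuffled over genes, the fit without a block recovered 76% and 99%, and the fit with slide as a block 86% and 98%. Of their calls, 1.13% and 6.60% were false. The simulated noise was normal and independent, with each gene's variance taken after eBayes had shrunk it in the fit with slide as a block. Outlying values on single arrays were not simulated. These shares therefore describe the simulated data and need not hold for the real arrays.

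The alternatives were quantile normalization, scaling to the median, the 75th percentile over probes well above background on all arrays, and normexp background correction (offset 50) with quantile or 75th percentile scaling. Normexp used the median spot signal in place of the mean. Further alternatives were the authors' table, no filter or a stricter filter on dim probes, eBayes with trend and robust, array weights, a replicate block, a slide block, the mean of a gene's probes or its first probe by name, and leaving out each array in turn. Calls were also made with treat at a fold change of 1.5 and with an ordinary test per gene at an unadjusted p under 0.05 and a fold of at least 2. Slide 1 alone, the fit without the arrays in the first slide position and the median signal in normexp were added after seeing the data.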

Results

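Gene expression was measured in BV2 cells, an immortalized line of mouse microglia, the resident macrophages of the brain. The cells had received 10 ng/ml of recombinant mouse IL-4 or PBS for 24 hr. IL-4 is a cytokine that drives the alternative, or M2, activation of macrophages, and the title of the study names M2 polarization of microglia as its subject. Each of the 6 samples was hybridised to a single-colour Agilent array of its own, 3 with IL-4 and 3 with PBS. The labels do not say whether the samples of a group came from separate cultures, so the p-values measure the spread between these samples, which may be technical. Between 34653 and 38649 of 39429 probes per array were well above background, the 75th percentile of the processed signal lay between 674 and 876, and no spot was saturated. The number of arrays limits the precision of every value. The 3 IL-4 arrays and PBS replicate 1 lay on slide 1, and PBS replicates 2 and 3 on slide 2.

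The comparison asked which mRNAs IL-4 changed. Arg1, encoding arginase 1 and widely used as a marker of alternative activation, rose 4.06-fold, a log2 fold change of 2.02 ± 0.16 (SE; adjusted p = 0.011, limma). Its log2 signal relative to the 75th percentile of the array was -3.41 ± 0.28 with PBS and -1.39 ± 0.17 with IL-4 (SD, n = 3 each). Cish and Socs1, feedback inhibitors of JAK and STAT signalling downstream of cytokine receptors, rose by 1.07 ± 0.11 and 1.17 ± 0.14 (adjusted p = 0.023 and 0.025). The chemokine gene Ccl12 rose by 1.15 ± 0.11 and the lectin gene Clec10a by 0.91 ± 0.12 (adjusted p = 0.013 and 0.026). Clec10a was picked after its values were seen. All 5 rises were also present between the IL-4 arrays and the PBS array of the same slide, at 2.29 for Arg1, 1.18 for Cish, 0.89 for Socs1, 1.05 for Ccl12 and 1.07 for Clec10a. Arg1 was still called with slide as a block (adjusted p = 0.032), whereas Cish, Ccl12, Clec10a and Socs1 were not (adjusted p = 0.072, 0.072, 0.12 and 0.13).

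Other genes commonly used as markers of IL-4 exposure did not pass the test. Mrc1, the mannose receptor, differed by 0.50 ± 0.12 (adjusted p = 0.057) and Chil3, the chitinase-like protein Ym1, by 0.61 ± 0.15 (adjusted p = 0.056). The log2 fold change was -0.14 ± 0.16 for Retnla, -0.69 ± 0.24 for Ccl17, -0.55 ± 0.21 for Ccl22, -0.14 ± 0.13 for Ccl24 and -0.39 ± 0.13 for Pdcd1lg2. For the transcription factor genes Irf4, Egr2 and Stat6 it was -0.14 ± 0.20, 0.01 ± 0.23 and -0.28 ± 0.14, and for the receptor gene Il4ra 0.32 ± 0.18, while a second, dimmer probe of Il4ra gave 0.92 ± 0.27. The adjusted p-values of these 9 genes ranged from 0.082 to 0.97. Some of them were dim. On the scale used for Arg1, the IL-4 and PBS means were -4.87 and -4.72 for Retnla and -5.06 and -4.51 for Ccl22. They were -4.47 and -4.33 for Irf4 and -4.19 and -3.50 for Ccl17. Retnla and Ccl22 were well above background on only 2 of 3 IL-4 arrays, so their fold changes are uncertain. Within slide 1 the differences were -0.24 for Ccl17, -0.22 for Ccl22, -0.20 for Pdcd1lg2 and -0.20 for Retnla. They were 0.74 for Mrc1, more than over all arrays, and 0.29 for Chil3, and neither gene was called with slide as a block. For Egr2, Irf4, Il4ra, Stat6 and Ccl24 they were 0.20, 0.09, 0.03, 0.01 and -0.03. Of the 42 genes tested in the list of the IL-4 response and alternative activation, 5 rose, 3 fell and 34 did not pass. The genes that fell were Cd83, Ch25h and Msr1. Adjusted over the list alone, 11 rose and 4 fell. The list as a whole did not pass, with a median log2 fold change of 0.07 (camera adjusted p = 0.12). With slide as a block its median was 0.07 and its adjusted p 0.0037, and with an estimated correlation the adjusted p was 0.97. The call with slide as a block was lost with an estimated correlation (adjusted p = 0.79). Without PBS replicate 3 the list passed (adjusted p = 0.042), and with the mean of each gene's probes its median was -0.0090. In the list of IL-4 receptor signalling and feedback, Cish and Socs1 rose and Ptpn6, the phosphatase SHP-1, fell by 0.73 on the log2 scale, while 20 of 23 genes did not pass. Adjusted over the list alone, 4 rose and 5 fell.

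**Figure D1:**
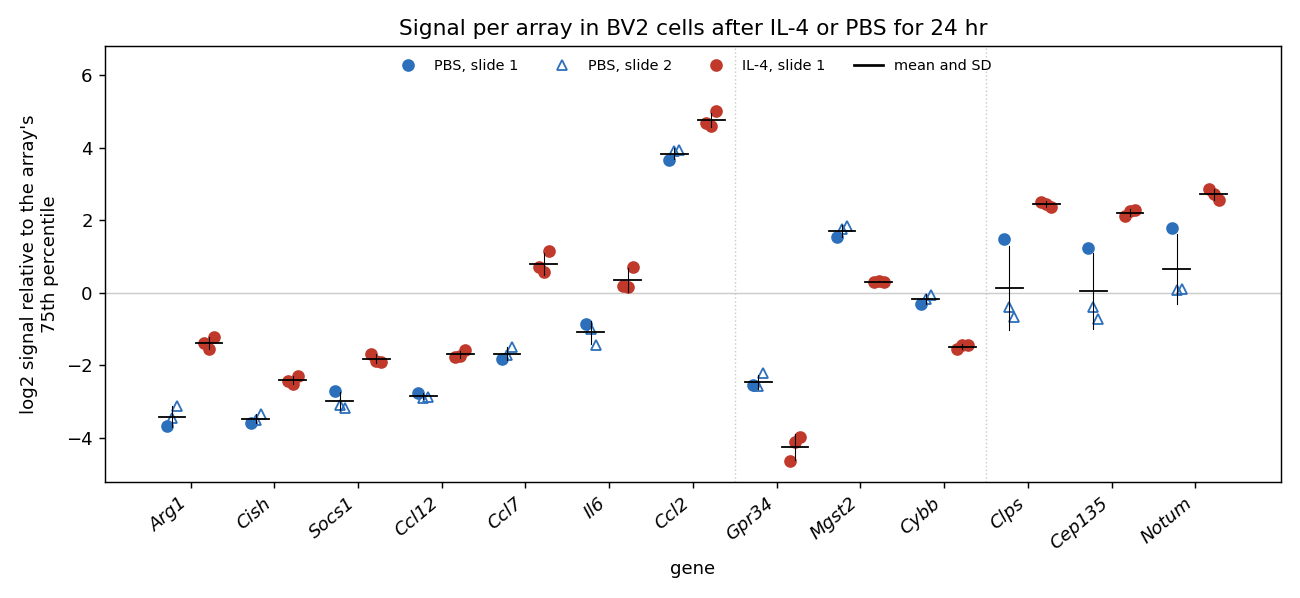
Log2 signal of 13 genes relative to the 75th percentile of each array (y axis) after PBS (blue) or IL-4 (red), with the mean and SD of 3 arrays as black lines, filled circles for slide 1 and open triangles for slide 2. PBS replicate 1 lies closer to the other PBS arrays than to the IL-4 arrays for Arg1 to Cybb. For Socs1 it lies 0.32 of the way from the mean of PBS replicates 2 and 3 to the IL-4 mean. For Clps, Cep135 and Notum it lies between the other PBS arrays and the IL-4 arrays, closer to the IL-4 arrays.

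Several chemokine and cytokine genes of classical, pro-inflammatory activation rose as well. Ccl7, a monocyte chemoattractant, had the largest rise among genes with a name that met the naming rule, 5.58-fold (log2 fold change 2.48 ± 0.17, adjusted p = 0.011). Il6 rose by 1.44 ± 0.21, Ccl2 by 0.93 ± 0.14 and the co-stimulatory receptor gene Cd40 by 0.84 ± 0.13 (adjusted p = 0.026, 0.028 and 0.032). Within slide 1 the differences were 2.63 for Ccl7, 1.20 for Il6, 1.11 for Ccl2 and 1.01 for Cd40. Ccl7 was still called with slide as a block (adjusted p = 0.044), whereas Ccl2, Cd40 and Il6 were not (adjusted p = 0.13, 0.13 and 0.21). Ptgs2, picked after its values were seen, rose by 0.76 ± 0.14. Tnf, Il1b and Nos2, the inducible nitric oxide synthase, had log2 fold changes of 0.09 ± 0.13, 0.09 ± 0.16 and 0.83 ± 0.25 and did not pass (adjusted p = 0.64, 0.73 and 0.072). In the pro-inflammatory list 5 of 34 genes rose and 0 fell. Adjusted over the list alone, 10 rose and 4 fell. The list passed upwards, with a median log2 fold change of 0.08 (camera adjusted p = 0.043). With an estimated correlation its adjusted p was 0.97, and with slide as a block, 0.0037 at a median of 0.08, or 0.79 with both. Without PBS replicate 1 the preset test gave an adjusted p of 0.21, and without IL-4 replicate 1 or PBS replicate 2, 0.081 and 0.058.

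Among 35 chemokine and chemokine receptor genes, Ccl7, Ccl12 and Ccl2 rose, and Ccl9 and Cxcr4 fell, Cxcr4 by 0.72 on the log2 scale (SE 0.12, adjusted p = 0.035). Adjusted over the list alone, 9 rose and 8 fell. Hbegf, a ligand of the epidermal growth factor receptor, rose by 1.06 ± 0.13 and the interleukin-1 receptor gene Il1r1 by 0.50 ± 0.11, whereas Il15 fell by 0.76 on the log2 scale (adjusted p = 0.025, 0.049 and 0.029). They were the only 3 of 38 genes for interleukins, growth and trophic factors that passed. Adjusted over that list alone, 5 rose and 1 fell. The list passed upwards only with slide as a block or on slide 1 alone (median 0.05, adjusted p = 0.031 and 0.032, and 0.79 for the block with an estimated correlation).

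Several genes of resting microglia and of macrophage identity fell. Gpr34, a lysophospholipid receptor of microglia, was 3.45-fold lower with IL-4 (log2 fold change -1.79 ± 0.19, adjusted p = 0.023). P2ry6, a nucleotide receptor, Golm1 and Tgfbr2, a receptor of TGF-beta, had log2 fold changes of -0.98 ± 0.14, -1.02 ± 0.14 and -0.61 ± 0.13 (adjusted p = 0.026, 0.026 and 0.049). Within slide 1 the differences were -1.69 for Gpr34, -0.96 for P2ry6, -0.73 for Golm1 and -0.37 for Tgfbr2, and none of the 4 was called with slide as a block (adjusted p = 0.13 to 0.35). These were the 4 of 29 homeostatic microglia genes that fell, and 0 rose. Adjusted over the list alone, 9 fell and 1 rose. The list passed downwards with a median of -0.28 (camera adjusted p = 0.013, and 0.97 as the adjusted p with an estimated correlation), and missed the threshold with the mean of each gene's probes (adjusted p = 0.056). Of 17 macrophage identity genes, 4 fell. They were Tyrobp, a signalling adaptor of myeloid receptors, at -0.95 ± 0.18, the lysozyme gene Lyz2 at -0.81 ± 0.14, Aif1, which encodes the microglial marker IBA1, at -0.72 ± 0.13, and the transcription factor gene Irf8 at -0.67 ± 0.12. Their differences within slide 1 were smaller, at -0.54, -0.55, -0.49 and -0.48 in that order. Adjusted over the list alone, 9 fell and 1 rose, and the median of the list was -0.41 (camera adjusted p = 0.014, and 0.97 as the adjusted p with an estimated correlation). Of 28 genes of disease-associated microglia, Timp2, Tyrobp, Ch25h and Lpl fell, at -1.34 ± 0.17, -0.95, -0.77 ± 0.15 and -0.56 ± 0.12, and none rose. A second, dimmer probe of Timp2 had a log2 fold change of -0.24 ± 0.10. The differences within slide 1 were -0.95 for the brightest probe of Timp2, -0.61 for Ch25h and -0.38 for Lpl. Adjusted over that list alone, 9 fell and 2 rose, and the list did not pass (camera adjusted p = 0.24). It passed downwards with quantile normalization (median -0.28, adjusted p = 0.012), with normexp and quantile (-0.25, adjusted p = 0.0095), with the authors' table (-0.25, adjusted p = 0.015) and without IL-4 replicate 1 (-0.19, adjusted p = 0.049). These lists, like 37 of all 39, were lower in PBS replicate 1 than in the mean of PBS replicates 2 and 3 (-0.16 as the median of the 39 list medians, -0.08 over all tested genes), with median differences of -0.16 for homeostatic microglia, -0.33 for macrophage identity and -0.26 for disease-associated microglia. Within slide 1 the medians of IL-4 minus PBS were -0.14, -0.20 and 0.02. With slide as a block the first 2 lists passed (adjusted p = 0.0026 and 0.028) and the third did not (0.44). Both of these calls were lost with an estimated correlation (adjusted p = 0.79 for each).

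Several genes of mitosis fell. Of 30 genes of the G2/M phase, 8 fell and 0 rose, and 19 fell when adjusted over the list alone. Mki67, a marker of proliferating cells, had a log2 fold change of -0.79 ± 0.14, the mitotic kinase gene Plk1 -0.76 ± 0.14, the cyclin gene Ccna2 -0.75 ± 0.16 and the kinetochore motor gene Cenpe -0.69 ± 0.12 (adjusted p = 0.037, 0.04, 0.049 and 0.036). Their differences within slide 1 were -0.51, -0.46, -0.41 and -0.64 in that order. The median of the list was -0.36 (camera adjusted p = 1.8e-04, and 0.97 as the adjusted p with an estimated correlation). It was -0.19 within slide 1, where the test with slide as a block gave an adjusted p of 1.4e-06 (0.32 with an estimated correlation), and PBS replicate 1 stood -0.24 from the mean of PBS replicates 2 and 3. Of 30 S phase genes, Tk1 and Prim1, chosen after their values were seen, fell, at -0.78 ± 0.10 and -0.62 ± 0.10, 0 rose, 2 rose and 2 fell when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.75). With slide as a block it passed upwards (median 0.15, adjusted p = 0.028, and 0.79 with an estimated correlation). The oxidative phosphorylation list passed downwards with a median of -0.21 over 58 genes (camera adjusted p = 0.013, and 0.97 as the adjusted p with an estimated correlation). Its members that fell were Uqcrb, a subunit of complex III, at -0.64 ± 0.13 and Ndufa5, a subunit of complex I, at -0.53 ± 0.11. The differences of these genes within slide 1 were -0.41 and -0.44. Adjusted over that list alone, 12 fell and 1 rose. Within slide 1 its median was -0.03, and with slide as a block it did not pass (adjusted p = 0.078). Nor did it pass without IL-4 replicate 2, IL-4 replicate 3 or PBS replicate 2 (adjusted p = 0.065, 0.081 and 0.058).

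Genes passed the test in both directions among p53 targets and among genes of cell fusion. Among 24 p53 targets the death receptor gene Tnfrsf10b rose by 1.39 ± 0.28, and Sesn1 and Zmat3 had log2 fold changes of -0.57 ± 0.12 and -0.53 ± 0.10 (adjusted p = 0.046, 0.046 and 0.042). Tnfrsf10b was 0.99 higher in PBS replicate 1 than in the mean of the other PBS arrays and differed by 0.73 within slide 1. Among 16 genes of cell fusion, Acp5, the tartrate-resistant acid phosphatase, rose by 0.65 ± 0.11, while the tetraspanin gene Cd81 and Tyrobp fell, Cd81 by 0.77 on the log2 scale (adjusted p = 0.035, 0.029 and 0.04). Adjusted over each list alone, 8 p53 targets rose and 7 fell, and 6 cell fusion genes rose and 5 fell.

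In the other lists, apart from markers of other cell types, at most 2 genes passed. Members outside the naming rule are given here because their counts were small, after their values were seen. The single genes that rose were Arg1 in arginine and polyamine metabolism, Cd74 in MHC class II presentation and Hilpda in the hypoxia response, and 2 immediate early genes rose, Nr4a1 and Zfp36. Genes that fell were Ifi27l2a in the type I interferon response, Msr1 among scavenger and phagocytic receptors, Tpp1 in the lysosome, Sat2 in polyamine metabolism, Abca1 among LXR targets and lipogenesis, Acadl and Lpl in fatty acid oxidation and PPAR targets, Gstm1 among NRF2 targets, Selenbp1 in the hypoxia response, and Timp2 in extracellular matrix and remodelling. None passed for NF-kB feedback, MHC class I presentation, cholesterol synthesis, glycolysis, the TCA cycle, MYC targets and ribosome biogenesis, the unfolded protein and integrated stress response, or heat shock. Adjusted over each list alone, at most 4 genes rose and at most 7 fell. None of these lists passed as a whole over all 6 arrays (camera adjusted p = 0.089 or above). With slide as a block 8 of them passed upwards, at adjusted p = 3.2e-04 for immediate early genes, 4.2e-04 for MYC targets, 0.0012 for heat shock, 0.0022 for cholesterol synthesis, 0.0038 for glycolysis, 0.007 for arginine and polyamine metabolism, 0.012 for the type I interferon response and 0.026 for the unfolded protein response. Their medians within slide 1 were 0.12 for glycolysis to 0.22 for MYC targets, and with an estimated correlation the adjusted p was 0.79 or above for each. Immediate early genes also passed with normexp and quantile or the 75th percentile (adjusted p = 0.033 and 0.047), without the arrays in the first slide position (0.033), and without IL-4 replicate 2, PBS replicate 2 or PBS replicate 3 (0.022, 0.023 and 0.042). Heat shock passed with normexp and the 75th percentile (0.047) and without PBS replicate 2 (0.032), and NRF2 targets passed downwards with normexp and quantile (0.040). The median lay below 0 while the test and the mean pointed upwards for glycolysis, extracellular matrix, chemokines and p53 targets (-0.10, -0.01, -0.06 and -0.0079). Median and mean lay below 0 while the test pointed upwards for the hypoxia response and astrocyte markers (medians -0.04 and -0.01). The mean alone lay below 0 for the type I interferon response and complement (-0.02 and -0.04) and above 0 for IL-4 receptor signalling (0.0087), and the median alone above 0 for blood cell markers (0.0061). Of 39 lists, 5 passed with the preset correlation and 0 with an estimated one, where the lowest adjusted p was 0.97.

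**Figure D2:**
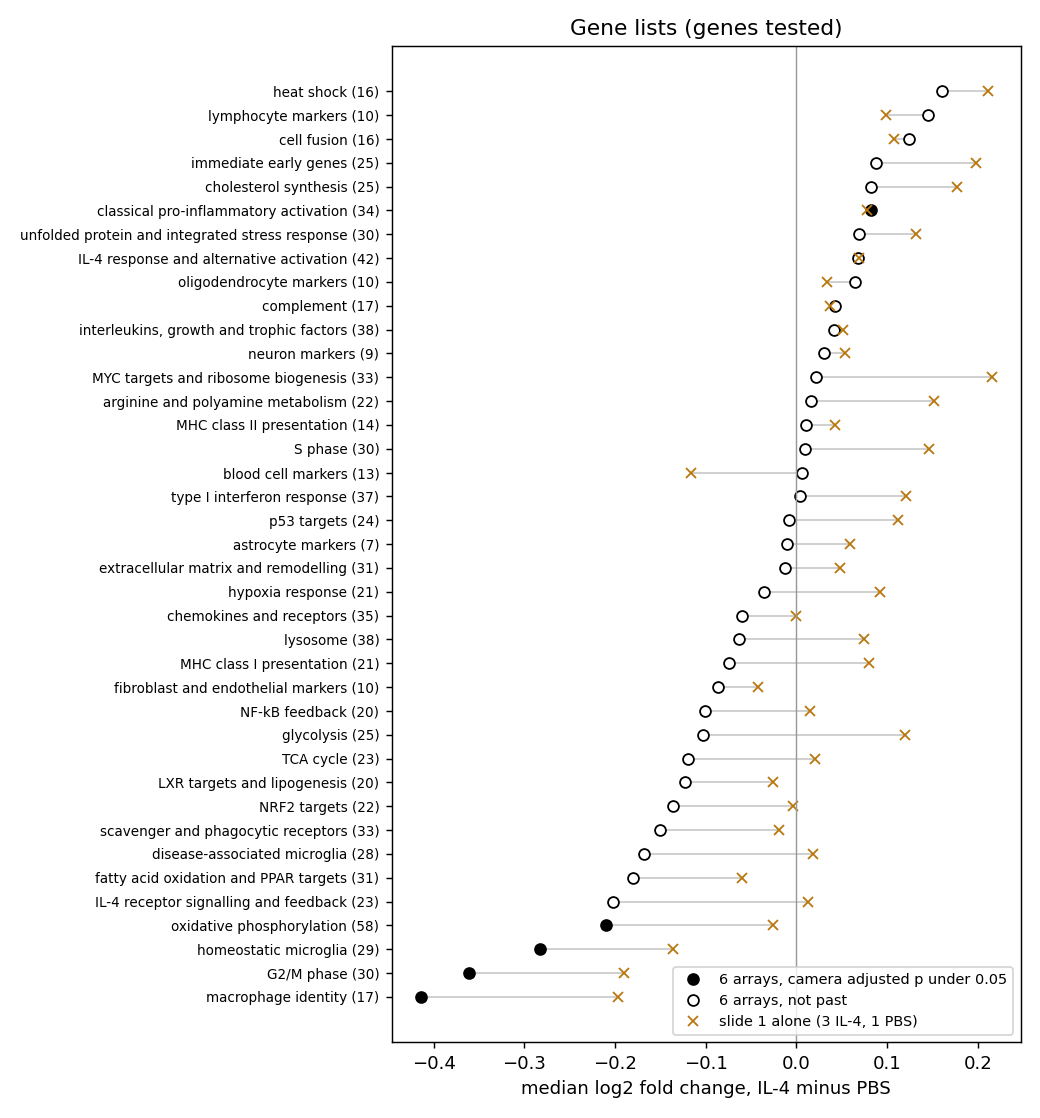
Median log2 fold change of IL-4 minus PBS (x axis) for each of 39 gene lists, with the number of genes tested in brackets, as circles over all 6 arrays (filled where camera with its preset correlation gave an adjusted p under 0.05) and crosses within slide 1. The 4 filled circles on the left are macrophage identity, G2/M phase, homeostatic microglia and oxidative phosphorylation.

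Over all genes, 6 arrays gave 29752 tested genes or unnamed transcripts, of which 997 differed between the groups. With IL-4, 240 of them were higher and 757 lower than with PBS, 89 and 69 by at least 2-fold. Since PBS replicates 2 and 3 lay on another slide, these counts can include differences between the slides. The largest falls that met the naming rule included those of Gpr34, Ctdsp2, Dcp1b, Mgst2, Timp2, Rbbp9, Mrpl34, Cybb and Gda. Mgst2, a microsomal glutathione S-transferase, and Cybb, the catalytic subunit of the phagocyte NADPH oxidase, had log2 fold changes of -1.41 ± 0.11 and -1.30 ± 0.11 (adjusted p = 0.011 each), and -1.22 and -1.17 within slide 1 (adjusted p = 0.044 and 0.051 with slide as a block). The log2 fold changes of Ctdsp2, Dcp1b, Timp2, Rbbp9, Mrpl34 and Gda lay between -1.42 for Ctdsp2 and -1.29 for Gda. The largest rises were those of Ccl7, Clps, Cep135, Notum, Arg1, Tiam1, Septin1, Slc22a17, Sis and Scube2. Except for Ccl7 and Arg1, these genes were also far higher in PBS replicate 1 than in the mean of PBS replicates 2 and 3, by 1.23 for Scube2 to 2.00 for Clps. The colipase gene Clps differed by 2.30 ± 0.48 over all arrays and 0.97 within slide 1, and Notum, an extracellular inhibitor of Wnt proteins, by 2.06 ± 0.41 and 0.94. A second probe of Clps had a log2 fold change of -0.60. Other probes also gave smaller values than the brightest for Septin1 (0.76 ± 0.20), Scube2 (0.51 ± 0.17), Gda (-0.78 ± 0.17), Rbbp9 (-0.85 ± 0.25), Tgfbr2 (-0.28 ± 0.10), Mki67 (-0.49 ± 0.10), Ctdsp2 (-0.51 ± 0.10 and -0.96 ± 0.11) and Uqcrb (-0.34 ± 0.10 and -0.46 ± 0.11). Among called genes with several tested probes, all probes moved in the same direction for 186 of 217 lowered genes and for 28 of 50 raised genes.

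The count of changed genes depended on the arrays used. With slide as a block, in limma, it was 9 (3037 at an unadjusted p under 0.05), and 3 of these, Arg1, Ccl7 and Mgst2, were also among the 997, so that every other called gene named here lost its call. Within slide 1, with 1 PBS array taken to vary like the IL-4 arrays, 0 genes passed in limma and 2595 had an unadjusted p under 0.05. Slide 2 held PBS samples only. Of the 996 called genes with a value on PBS replicate 1, 996 differed in the same direction within slide 1, although the calls themselves used that array. The difference within slide 1 reached at least 0.5 of the log2 fold change over all arrays for 757 of 757 lowered and 204 of 239 raised genes. It did so for 69 of 69 genes lowered and 56 of 88 raised at least 2-fold (63.6%). A call required the PBS arrays to differ little relative to the fold change, which disfavoured genes with a small difference within slide 1. These shares are therefore no independent support. Without PBS replicate 1 the count was 12651, but there all IL-4 arrays lay on slide 1 and all PBS arrays on slide 2. Slide and treatment cannot be told apart in that fit. Without any 1 of the other arrays the count was 0 for IL-4 replicate 1 and PBS replicate 2 (7032 and 6088 genes at an unadjusted p under 0.05). It was 1 for IL-4 replicate 3, 2 for IL-4 replicate 2 and 3 for PBS replicate 3. Normexp background correction with the 75th percentile gave 2032 raised and 2026 lowered genes in place of 240 and 757.

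The arrays resembled each other by slide as well as by treatment. Pearson correlations of log2 signal across genes, which are not independent replicates, were 0.997 to 0.998 among the IL-4 arrays and 0.997 between PBS replicates 2 and 3. PBS replicate 1 correlated at 0.994 to 0.997 with the IL-4 arrays of its slide and at 0.989 with both other PBS arrays. The first principal component held 74.4% of the variance. The SD across genes of the log2 difference between PBS replicate 1 and the mean of PBS replicates 2 and 3 was 0.413, against 0.229 between the IL-4 mean and PBS replicate 1 and 0.242 between PBS replicates 2 and 3.

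**Figure D3:**
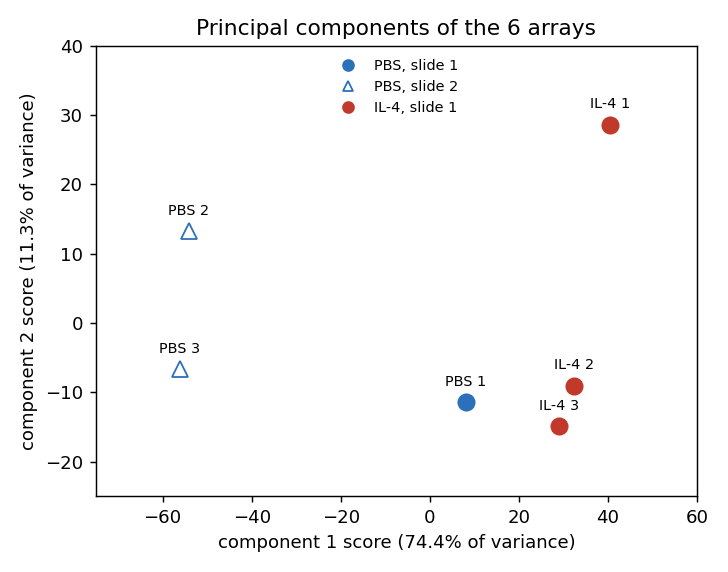
Scores of the 6 arrays on the first principal component (x axis, 74.4% of variance) and the second (y axis, 11.3%) of log2 signal over genes, with IL-4 in red, PBS in blue, filled circles for slide 1 and open triangles for slide 2. PBS replicate 1 scores 8.12 on the first component, between the IL-4 arrays (29.1 to 40.6) and PBS replicates 2 and 3 (-54.1 and -56.1).

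Markers of other cell types gave signals well above background without a called rise. For at least 1 probe on all 6 arrays this held for 8 of 11 listed astrocyte markers, among them Aldoc, Fgfr3 and Gfap, 9 of 12 neuron markers (Snap25, Syn1 and Tubb3), 10 of 10 oligodendrocyte markers (Mog, Sox10 and Mobp), 9 of 12 fibroblast and endothelial markers (Pecam1, Kdr and Cldn5), 10 of 12 lymphocyte markers (Lck, Cd3e and Ncr1) and 9 of 18 blood cell markers (Pf4, Slc4a1 and Itga2b). For the macrophage identity list it was 17 of 18. On each array 87.9% to 98.0% of all probes were well above background, so these counts do not show that a marker was expressed. The median log2 level of the tested markers relative to the 75th percentile was -2.29 for astrocyte, -3.45 for neuron and -2.92 for oligodendrocyte markers. It was -3.58 for fibroblast and endothelial, -2.73 for lymphocyte and -2.77 for blood cell markers, against 0.65 for macrophage identity. Single markers named above were far brighter than these medians. The IL-4 and PBS means were 3.40 and 3.48 for Pecam1, 3.10 and 3.41 for Pf4 and 3.05 and 3.30 for Aldoc. Others were dim, such as Cldn5 at -3.43 and -3.34 and Tubb3 at -2.57 and -2.59. Of the markers of other cell types, 1 passed the test, the blood cell marker S100a8, which fell by 0.97 on the log2 scale (SE 0.19, adjusted p = 0.042). Adjusted over each list alone, at most 3 rose and at most 2 fell. The lists did not pass as a whole, with camera adjusted p-values from 0.38 for lymphocyte markers to 0.88 for astrocyte markers, except that lymphocyte markers passed upwards on slide 1 alone (median 0.10, adjusted p = 0.048). Mog and Cd3e, at log2 fold changes of 0.82 ± 0.25 and 0.91 ± 0.23 (adjusted p = 0.072 and 0.058), were 0.94 and 0.75 higher in PBS replicate 1 than in the mean of the other PBS arrays.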

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

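Slide 1 alone, the fit without the 2 arrays in the first slide position and the median signal in normexp were chosen after seeing the data. Counts of called genes moved with nearly every setting, while directions of called named genes did not, except for Clps with the first probe by name (-0.60, where that probe is a different one). The cause was not tested unless given. Of the 997 called genes, 996 had groups that did not overlap. For these, leaving out arrays or taking slide as a block could not reverse the direction of the same probe. The stable directions under those settings are therefore no independent support. Over all alternatives, 1824 values of named genes comprised 1227 on the same side of the threshold, 496 weaker, 67 stronger and 34 reversed. The G2/M phase and macrophage identity lists passed under every alternative that used camera with the preset correlation. All of these drew on the same 6 arrays and 2 slides, so they are no independent support. With an estimated correlation in camera neither list passed (adjusted p = 0.97 for each). Array weights and eBayes with trend and robust do not enter camera as run here, so they could not change its result. IL-4 replicate 1 and PBS replicate 2, with the fewest probes well above background, limited how many dim genes entered the test. Without them 31323 and 30744 genes were tested, against 29752 with all arrays and 29753 to 29764 without 1 of the others.

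The genes changed by IL-4 numbered 997, with 240 raised, 757 lowered and 89 genes raised at least 2-fold. In that order they numbered 2637, 833, 1804 and 230 with quantile normalization, 1733, 531, 1202 and 218 with median scaling, and 2299, 674, 1625 and 175 with the authors' table. They numbered 3808, 1830, 1978 and 481 with probes well above background on all arrays and, for the first 3 counts, 3685, 1432 and 2253 with eBayes trend and robust. With genes lowered at least 2-fold (69) as the last count, they numbered 523, 107, 416, 33 and 45 with the 75th percentile over detected probes, 3096, 988, 2108, 169 and 25 with normexp and quantile, 4058, 2032, 2026, 374 and 23 with normexp and the 75th percentile, 15, 5, 10, 5 and 10 without a filter (9653 at an unadjusted p under 0.05), 14200, 6404, 7796, 1307 and 127 with array weights, and 9, 6, 3, 6 and 3 with slide as a block. With the mean of a gene's probes the first 4 counts were 605, 117, 488 and 42. All 5 counts were 0 in limma on slide 1 alone (2595 at an unadjusted p under 0.05) and without the arrays in the first slide position (3565), where fewer arrays were used. Treat at a fold change of 1.5 in limma called 0 genes, against 10152 at an unadjusted p under 0.05, and the ordinary test with a fold of at least 2 gave 425. Leaving out 1 array in turn gave 0 to 12651 changed, 0 to 5810 raised, 0 to 6841 lowered, 0 to 1441 raised and 0 to 192 lowered at least 2-fold. The highest counts came without PBS replicate 1, where 995 of the 997 calls were shared. In that fit all IL-4 arrays lay on slide 1 and all PBS arrays on slide 2. The shared calls therefore do not separate an effect of IL-4 from a difference between slides. Counts of 0 changed genes came without IL-4 replicate 1 or PBS replicate 2 (7032 and 6088 in limma at an unadjusted p under 0.05).

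With the replicate number as a block, counts were 3770 for genes changed by IL-4, 1804 for those raised, 1966 for those lowered and 541 for genes raised at least 2-fold, the 997 calls were all among them, and the pro-inflammatory list had a median of 0.082 (adjusted p = 0.0501). Deviations of same-numbered arrays from their group means correlated across genes at 0.083, -0.016 and 0.296. IL-4 replicates 1 and 3 correlated best with the PBS array of the same number, and IL-4 replicate 2 with PBS replicate 1 (0.035). The deviations of the PBS arrays also hold the difference between the slides, so these values cannot decide whether samples were paired. The labels state no pairing.

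Of the lists, 15 passed with slide as a block and 16 on slide 1 alone, and 0 with camera at an estimated correlation or with fry (lowest adjusted p 0.97 and 0.19), whereas fry's mixed test, of change in either direction, passed for 35 of 39 (lowest adjusted p 8.4e-05). The median of the IL-4 response list was 0.069 with slide as a block and on slide 1 alone, where it passed (adjusted p = 0.0037 and 0.0047), -0.0090 with the mean of a gene's probes, and 0.0010 to 0.13 without 1 array in turn. The pro-inflammatory list did not pass with normexp and quantile (median 0.023), without a filter (0.031), with probes well above background on all arrays (0.079), without the arrays in the first slide position (0.10), or with an estimated correlation or fry (0.082, adjusted p = 0.97 and 0.26). Its median was 0.012 to 0.11 without 1 array in turn, and its adjusted p ranged from 0.0037 to 0.97 over these alternatives.

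Reversed log2 fold changes, other than that of Clps, belonged to genes that were not called. They were -0.0035 with normexp and quantile, -0.0011 with normexp and the 75th percentile and -0.020 with array weights for Tubb3, and -0.0043 with normexp and the 75th percentile and -0.15 with array weights for Egr2. Array weights gave 0.022 for Pecam1 and -0.050 for Lck. Slide as a block and slide 1 alone both gave 0.088 for Irf4, 0.0059 for Stat6, 0.011 for Syn1 and 0.0020 for Ncr1. Gfap stood at -0.071 with the mean of probes and -0.50 with the first probe, and Kdr at -0.078 with the first probe. Without the arrays in the first slide position Pecam1 stood at 0.20 and Ccl24 at 0.0036. Leaving out 1 array in turn gave -0.27 to 0.0036 for Retnla, -0.30 to 0.040 for Irf4, -0.22 to 0.073 for Pecam1, -0.25 to 0.18 for Egr2, -0.029 to 0.15 for Tnf, -0.038 to 0.056 for Tubb3, -0.028 to 0.16 for Lck and -0.059 to 0.24 for Il1b. It gave 1.89 to 2.17 for Arg1, 2.31 to 2.60 for Ccl7 and -1.92 to -1.59 for Gpr34.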

Other observations

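The tests of a wrong label, of the slide and of a general stimulus for the inflammatory genes, and the count of genes with a single tested probe, were chosen after the result was seen, as were the genes singled out in the next paragraph. The probe comparison for genes with several probes and the splits of the arrays were chosen before.

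Single genes of antigen presentation, early transcription and lipid handling passed the limma test outside the named groups. Cd74, the invariant chain of MHC class II, rose by 0.84 ± 0.13 (adjusted p = 0.033) and differed by 1.09 within slide 1, while the MHC class II list had a median of 0.01. Zfp36, whose product destabilises cytokine mRNAs, and the nuclear receptor gene Nr4a1 rose by 0.71 ± 0.12 and 0.69 ± 0.11 (adjusted p = 0.035 and 0.029). Abca1, a cholesterol exporter, had a log2 fold change of -0.89 ± 0.14 and Gstm1, a glutathione S-transferase, -0.90 ± 0.16 (adjusted p = 0.03 and 0.035), and within slide 1 they stood at -0.62 and -0.62. None of these 5 genes was called with slide as a block (adjusted p = 0.071 for Cd74 to 0.25 for Gstm1).

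PBS replicate 1 lay closer to the IL-4 arrays of its slide than to the other PBS arrays. On a scale from 0 at the mean of PBS replicates 2 and 3 to 1 at the IL-4 mean, its median position was 0.753 over 1634 genes at least 2-fold different between these arrays, with 88.1% past the middle, against 0.954 to 0.995 for each IL-4 array left out and placed likewise. A wrong label is argued against by 6 of 13 members of the IL-4 response list raised against PBS replicates 2 and 3 alone (Arg1, Ccl12, Cish, Clec10a, Mrc1 and Socs1), which stood below the middle by more than the SD between arrays, as 0 of 11 to 16 did on each IL-4 array so placed, although the median of the 13 was 0.566. Where its brightest probe differed at least 2-fold between PBS replicate 1 and the other PBS arrays, a gene's other probes differed by a median of -0.045 of that amount (144 genes). Of these genes, 139 were higher in PBS replicate 1 (ratio -0.047) and 5 were lower (ratio 0.15, with 80% in the same direction). For the genes higher in PBS replicate 1, this argues against a difference in transcript level and goes with a slide effect on single probes. For genes lower in PBS replicate 1 it cannot decide, since 5 are too few. For called genes at least 2-fold different between IL-4 and PBS, the ratio was 0.49 for those lower (19) and 0.067 for those higher (18) with IL-4. For 373 further genes with 1 tested probe a slide effect and a difference in transcript level cannot be told apart, and degraded RNA or labelling may also act on single probes.

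For the rise of the inflammatory gene Ccl7 with IL-4, a difference between the slides as the whole cause is argued against, since with slide as a block it was called at 2.63 ± 0.23, against 2.48 ± 0.17 without the block (adjusted p = 0.044, with 1 PBS array on slide 1). For Il6, Ccl2, Cd40 and Ccl12 the block gave 1.20 ± 0.27, 1.11 ± 0.17, 1.01 ± 0.15 and 1.05 ± 0.12, against 1.44 ± 0.21, 0.93 ± 0.14, 0.84 ± 0.13 and 1.15 ± 0.11 without it, at least 4.44 standard errors above 0, which goes against the slide as the whole cause, but it stays open, since that PBS array carries the comparison and the calls ended as standard errors grew and the folds of Il6 and Ccl12 shrank (adjusted p = 0.21, 0.13, 0.13 and 0.072). Besides IL-4 itself, another component of its preparation, which was not tested, and a general inflammatory stimulus such as endotoxin stay open, although the highest log2 fold change in the NF-kB feedback list was 0.47 (Nfkb1), below the smallest of the 5 rises, 0.84 for Cd40. Of its 20 members 0 rose and 0 fell in limma, 2 rose and 2 fell when adjusted over the list alone, and their median log2 fold change was -0.10. There were 1 or 2 rises with normexp, the stricter filter, trend and robust, array weights, the replicate block and without PBS replicate 1. With either form of normexp 1 rose and 2 fell, and with quantile normalization 0 rose and 2 fell. Tnf and Il1b stood at 0.09 ± 0.13 and 0.09 ± 0.16, whereas Nos2 stood at 0.83 ± 0.25, near the value of Cd40, and at 0.24 within slide 1.

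Splits of the 6 arrays into 3 and 3 number 10, too few for a share under 0.05. The real split gave 997 changed genes, 240 raised, 757 lowered, and 89 raised and 69 lowered at least 2-fold, 1 of 10 splits for each, and the highest of the other splits was 0 in limma (54 to 3365 genes at an unadjusted p under 0.05). For the gene lists 7 of 10 splits gave as many as the 5 of the real split, the highest 15. The 3 other splits that kept the arrays of slide 2 together gave 0, 0 and 13 lists, and those that parted them 3 to 15. With slide as a block the real contrast gave 15 lists and 9 genes.

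In the fit with slide as a block, 6 of the 9 called genes were not called over all arrays, and in these PBS replicate 1 lay beyond the means of both the IL-4 arrays and the other PBS arrays. For Cyp2f2 it stood at -8.76, against -4.04 for the mean of the IL-4 arrays and -3.97 for the mean of PBS replicates 2 and 3. For Dock4 the values were -2.23, -0.45 and -0.67. An unnamed transcript among the 6 stood at the same -8.76 as Cyp2f2 on PBS replicate 1. Both values may therefore be the lower limit of that array rather than measured levels.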
